A study of Hevea brasiliensis with 4 samples.

How the data were processed

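Small RNAs were sequenced from leaves of the rubber tree Hevea brasiliensis, from 2 clones (PB217 and PB260, which are vegetatively propagated cultivars) and 2 leaf stages (mature and young). The labels give 1 library per clone and leaf stage, 4 libraries in all, with no replicate of any group. Per the labels' protocols, total RNA was resolved on a 15% polyacrylamide gel, RNA of 18 to 30 nt was cut out, adaptors were ligated to both ends in turn, and the amplified cDNA was sequenced on a HiSeq2000. Each library carried a barcode in its 5' adaptor. Both mature leaf libraries carried AG and both young leaf libraries carried CT, so leaf stage and barcode changed together in every comparison of young with mature leaves.

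The deposited files hold raw read counts per distinct sequence, 1 file per library, with no header. The values themselves show that adaptor and barcode had been trimmed from most reads and identical reads merged. Pieces of the 5' adaptor with the barcode were still listed, at up to 5976 RPM in PB217 young leaves. Sequences ranged from 18 to 40 nt, and the lowest count listed was 2 in every library. Sequences read once are thus not listed, a sequence missing from a library had 0 or 1 read, and the sum of a file is the total of its listed reads rather than the full depth. The trimming tool and any other filter are not given in the sources used here. Listed reads numbered 20587035 in PB217 mature, 12828573 in PB217 young, 19873147 in PB260 mature and 15917107 in PB260 young leaves, over 1080286, 924327, 1305091 and 1774175 distinct sequences. Reads outside 18 to 30 nt made up at most 0.736% of a library. At these totals 10 reads per 1000000 listed reads (RPM) stood for more than 100 reads, and exact intervals at 95% were computed for shares (Clopper-Pearson) and for ratios of 2 libraries (conditional binomial). PCR reads without molecular identifiers are not independent molecules, so all intervals cover counting error only.

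No genome sequence was used here. The gene table of the rubber tree assembly ASM3005281v1 pairs locus tags with symbols and holds neither sequences nor microRNA genes, so no small RNA was placed on a chromosome and the genomic position of each is not analysed here. MicroRNA families were instead identified by sequence. Before the data were examined, mature sequences of 53 families were written down from general knowledge of plant small RNAs. They comprised 33 microRNA or trans-acting siRNA families in 8 lists (phase change, auxin, leaf and meristem development, copper, phosphate with sulfate and nitrogen, small RNA pathway, defence and MYB, other conserved families), 5 families known from Brassicaceae as a negative control, 9 passenger strands, and 6 rRNA and tRNA fragments as signs of RNA breakdown. A read of 18 to 24 nt joined a family when it matched a listed sequence over at least 18 nt with at most 2 mismatches and a 5' end shifted by at most 2 bases. The miR482/miR472/miR2118 group was recognised by a sequence motif, and rRNA and tRNA fragments by exact identity to part of the listed stretch. Reads that matched 2 families equally well were left unassigned. A family value therefore sums variants that different loci can share, and it cannot separate near-identical members of one family.

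Counts were scaled to RPM of all listed reads. With 1 library per group, a ratio between 2 libraries has no replicate check, and it is given with its counting interval and no p-value. Comparisons across all 4 libraries used edgeR's quasi-likelihood F test on the deposited counts with clone and leaf stage in the model and library sizes set to the listed reads. Both clones then act as the 2 samples of each leaf stage, and both leaf stages as the 2 samples of each clone, with 1 residual degree of freedom. Such a p-value measures whether the change was alike in both pairs of libraries, not the spread between plants. Families needed at least 10 reads over the 4 libraries, and single sequences a mean of at least 5 RPM. Adjusted p-values follow Benjamini and Hochberg with a threshold of 0.05, and standard errors were derived from the F statistic. The median log2 ratio of the commonest sequence of each list member was placed among 10000 random lists of unlisted 20 to 22 nt sequences matched within 0.5 log2 units of mean abundance, for lists of at least 3 measured members. These percentiles describe the libraries and are no test.

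The choice of families and sequences to name was fixed before the data were examined. A family could be named with at least 10 RPM in at least 1 library, and those at least 2-fold apart in the same direction in both pairs lead each comparison. Of sequences outside the families, the 3 commonest of 21, 22 and 24 nt were named, together with the 3 with the largest mean log2 ratio in each direction for leaf stage and for clone, among those with at least 100 RPM in a library and the same direction in both pairs. Families that changed at least 2-fold in opposite directions in the 2 clones were also named. Bases of 2 sequences that the rule selected are not given because their origin in the rubber tree was not established.

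Alternatives were scaling by edgeR's TMM factors, by DESeq2 size factors, by microRNA family reads and, added after seeing the data, by reads outside listed rRNA, tRNA and adaptor sequences. Others were the DESeq2 Wald test, a fit without the clone or leaf stage block, other filters and mismatch limits, each library left out in turn, and size classes counted by distinct sequences, without rRNA and tRNA, without these and sequences like tRNA-Ala (holding GGATGTAGCTCA, added after seeing the data), or without the 100 commonest sequences. The Wald test used DESeq2's own size factors in place of the listed reads, so it changed test and scaling together. The edgeR tests were checked on simulated counts with known changes. At a dispersion of 0.05, the leaf stage test over 47 families recovered 2 of 7 changes of 1 log2 unit, 7 of 7 of 2 units and 5 of 6 of 3 units with 1 false call. At a dispersion of 0.3 it recovered none of these, and the clone test over 47 families recovered 1 of 7 changes of 2 units and 1 of 6 of 3 units. Over 17861 sequences at a dispersion of 0.05, the leaf stage test recovered 67 of 67 changes of 2 units, and the clone test 65 of 67. At a dispersion of 0.3 these became 1 of 67 and 0 of 67, and of changes of 3 units the tests recovered 8 of 66 and 2 of 66. Both dispersions were set by choice and the dispersion of these libraries is not given. The recovery at 0.05 is thus not the power of the tests run here. Of 3450 listed sequences altered at up to 2 bases, 99.97% were assigned to their own family, and 0 of 20000 random sequences of 21 nt were assigned to any. R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 were used.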

Results

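Small RNA libraries from mature and young leaves of the rubber tree clones PB217 and PB260 were compared, with 1 library for each clone and leaf stage. Listed reads numbered 20587035 in PB217 mature, 12828573 in PB217 young, 19873147 in PB260 mature and 15917107 in PB260 young leaves. The values were raw reads per distinct sequence, without sequences read once, and are given as RPM (reads per 1000000 listed reads). There were no replicates, so the ratios between 2 libraries have no replicate check and their 95% intervals cover counting error only. Of 33 microRNA and trans-acting siRNA families looked for, 27 reached 10 RPM in at least 1 library. Their reads made up 3.09% of the listed reads in PB217 mature, 2.89% in PB217 young, 3.92% in PB260 mature and 7.12% in PB260 young leaves.

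The 4 libraries differed first in their length profile. Plant microRNAs are mostly 21 or 22 nt long, and siRNAs that guide DNA methylation are mostly 24 nt. The 24 nt class took 38.8% of reads of 18 to 30 nt in PB260 young leaves, against 20.4% in PB260 mature, 14.2% in PB217 young and 13.0% in PB217 mature leaves. Part of the 24 nt class were fragments like the 5' part of tRNA-Ala, of which 3 sequences of 24 nt took 15.2% of all listed reads in PB260 young leaves and 1.23%, 0.290% and 1.58% in PB217 mature, PB217 young and PB260 mature leaves. Without such sequences and the listed rRNA and tRNA, an alternative added after seeing the data, the 24 nt share was 28.3% in PB260 young leaves and 12.2%, 14.5% and 19.8% in the others in that order. The 21 nt class took 23.4% in PB260 young leaves and 17.0%, 17.2% and 16.9% in PB217 mature, PB217 young and PB260 mature leaves. The exact binomial 95% interval was 38.74% to 38.79% for the 24 nt share in PB260 young leaves, and no wider in the other libraries. Counted by distinct sequences, the 24 nt class made up 51.8% in PB260 young and 50.4% in PB260 mature leaves, and 40.2% and 39.8% in PB217 young and mature leaves, so the excess of PB260 young over PB260 mature leaves shrank while PB260 stayed above PB217. Distinct 24 nt sequences began with A in 63.1% of cases in PB217 mature, 59.6% in PB217 young, 66.9% in PB260 mature and 58.4% in PB260 young leaves. Counted by reads, A began 47.4%, 54.9%, 52.6% and 35.4% of the 24 nt class in the same order, and G began 47.2% in PB260 young leaves. Reads of 21 nt began with U, the usual first base of plant microRNAs, in 31.9%, 29.2%, 41.4% and 54.9% of cases in the same order.

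**Figure D1:**
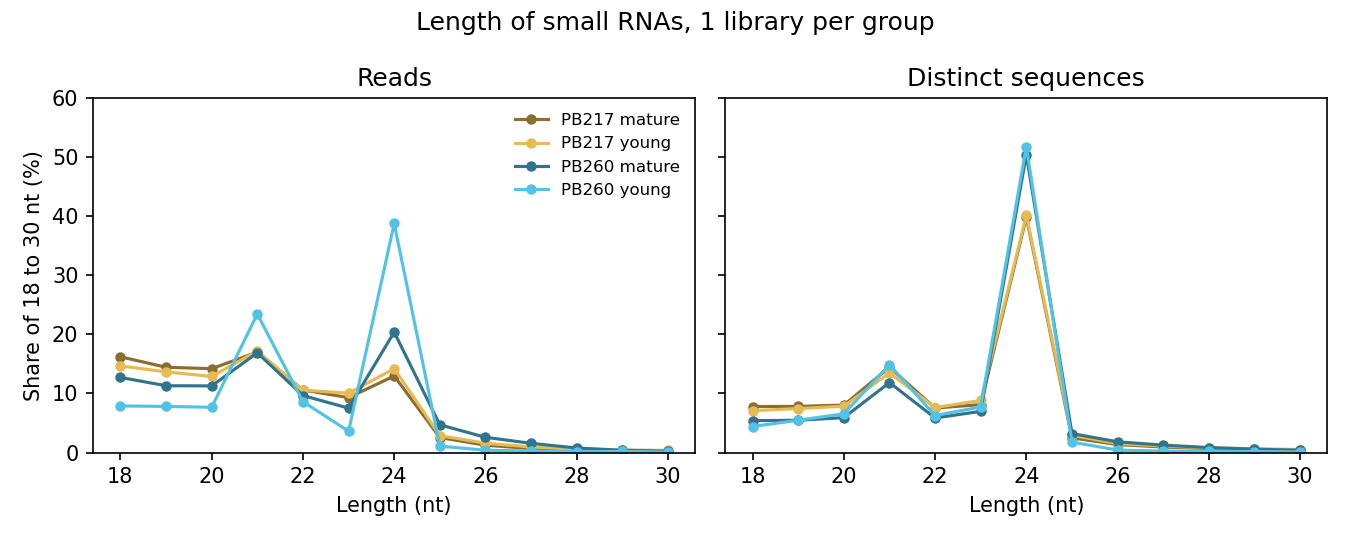
Share of reads (left) and of distinct sequences (right) by length in nt, in percent of 18 to 30 nt, with 1 line per library. By reads, the PB260 young library has the highest points at 21 nt (23.4%) and 24 nt (38.8%), and by distinct sequences all 4 libraries peak at 24 nt.

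Short reads of 18 to 20 nt went the other way. They took 44.8% of reads in PB217 mature, 41.2% in PB217 young, 35.3% in PB260 mature and 23.4% in PB260 young leaves. Fragments of the 5' part of tRNA-Ala measured 14991 RPM in PB217 mature, 8858 in PB217 young, 18374 in PB260 mature and 104557 in PB260 young leaves. By contrast, 5.8S rRNA fragments were lowest in PB260 young leaves, at 15640 RPM against 29057, 37252 and 35340 in PB217 mature, PB217 young and PB260 mature leaves. The 10 commonest sequences took 23.97% of the reads in PB260 young leaves and 8.58%, 6.01% and 8.89% in those same 3 libraries. The PB260 young library thus stood apart in its makeup, and TMM and DESeq2 scaling moved every log2 ratio of PB260 young to PB260 mature leaves by +1.62 and +1.79, and every ratio of PB260 young to PB217 young leaves by +1.69 and +1.89. Scaling by microRNA family reads moved them by −0.86 and −1.30. The other pairs moved by at most 0.34.

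The comparison of young with mature leaves asked which small RNAs follow leaf age in both clones. The miR165/miR166 family, which targets the class III HD-ZIP genes of the upper leaf side, was 7.38-fold higher in young leaves of PB217 (786 against 5802 RPM) and 7.89-fold higher in PB260 (941 against 7424). The miR319 family, which targets TCP genes of leaf growth, was 2.59-fold higher in young leaves of PB217 and 29.5-fold higher in PB260. The phosphate starvation family miR399 was 12.6-fold higher in young leaves of PB217 (1.94 against 24.5 RPM) and 5.26-fold higher in PB260 (5.69 against 29.9). The miR393 family, which targets auxin receptors, was 3.45-fold higher in PB217 (11.8 against 40.6 RPM) and 2.26-fold higher in PB260 (18.3 against 41.3). On the other side, miR530 was 3.67-fold lower in young leaves of PB217 and 9.31-fold lower in PB260. These 5 families kept their direction in both clones under each other scaling tried. The log2 ratio of miR393 in PB260 was 0.39 with exact matches only and 0.31 under scaling by microRNA reads, so that it no longer met the 2-fold rule there, and miR399 stayed under 10 RPM with exact matches only. Also lower in young leaves were miR397 (laccases) at 5.61-fold and 3.39-fold, miR167 (auxin response factors) at 2.25-fold and 2.45-fold, and miR168 (ARGONAUTE1) at 2.19-fold and 2.11-fold, in PB217 and PB260 respectively. In PB260 the direction of miR167 and miR168 flipped under TMM and DESeq2 scaling, and that of miR397 under DESeq2 scaling. Brassicaceae control families at levels like those of miR399 and miR393 rose in PB217 too. From mature to young leaves, miR161 went from 11.6 to 59.5 RPM, miR163 from 0.874 to 16.6 and miR158 from 24.5 to 35.5. There miR173 had 7 and 2 reads and miR857 had 0. In PB260 miR158 and miR161 fell, and miR163, miR173 and miR857 had 0 reads. A rise at these levels in PB217 was thus not particular to the listed microRNAs.

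By list, the leaf and meristem group had 7 measured families, of which miR165/miR166 and miR319 were at least 2-fold higher in young leaves of both clones and 5 did not move by 2-fold in the same direction in both. Among those, miR159, which targets GAMYB-like genes, measured 6369 and 9553 RPM in PB217 mature and young leaves, and 7640 and 27579 in PB260. The miR396 family, which targets growth-regulating factors, was 2.11-fold lower in young leaves of PB217 and close to equal in PB260, at 18363 and 18003 RPM in mature and young leaves, where other scalings put it on either side. Of 5 auxin families, miR393 was higher and miR167 lower in both clones, with the flip of miR167 in PB260 given above, and miR160, miR390 and the TAS3 tasiR-ARF were neither. Both phase change families were outside the 2-fold rule. The miR156/miR157 family, which targets SPL genes, measured 339 and 299 RPM in PB217 mature and young leaves and 539 and 693 in PB260. The miR172 family, which targets AP2-like genes, was 10.2-fold lower in young leaves of PB217 (142 against 14.0 RPM), and in PB260 its log2 ratio was −0.86, which turned positive under TMM and DESeq2 scaling.

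The copper-related families were lower in young leaves of both clones, miR397 by the folds above and miR408 with log2 ratios of −0.99 and −1.44, of which the PB260 values turned positive under DESeq2 scaling and that of miR408 also under TMM. Of the 3 measured phosphate, sulfate and nitrogen families only miR399 met the rule. The sulfate starvation family miR395 was 5.25-fold higher in young leaves of PB217 (265 against 1392 RPM), and in PB260 measured 128 and 78.0 RPM, a log2 ratio of −0.71 that turned positive under TMM (0.91) and DESeq2 scaling (1.08). The miR169 family, which targets NF-YA genes, measured 319 and 221 RPM in PB217 mature and young leaves, and 478 and 70.7 in PB260. Of these reads, 21 of 6575 in PB217 mature and 326 of 1126 in PB260 young leaves were exact matches. With exact matches only, miR169 was higher in young leaves of both clones (1.02 against 2.57 RPM in PB217, 0.855 against 20.5 in PB260). In the small RNA pathway list miR168 met the rule, and miR162 (DCL1) and miR403 (ARGONAUTE2) did not. In the defence and MYB list neither measured family met it, with miR482/miR472/miR2118 at 1533 and 647 RPM in PB217 mature and young leaves and 1488 and 1405 in PB260. In the list of other conserved families miR530 met the rule, and miR535 and miR479 did not. Across all 27 families, 6 were higher and 21 lower in young leaves of PB217, and 15 were higher and 12 lower in PB260. The PB260 split became 24 and 3 under TMM, 25 and 2 under DESeq2 scaling, and 12 and 15 under scaling by microRNA reads.

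**Figure D2:**
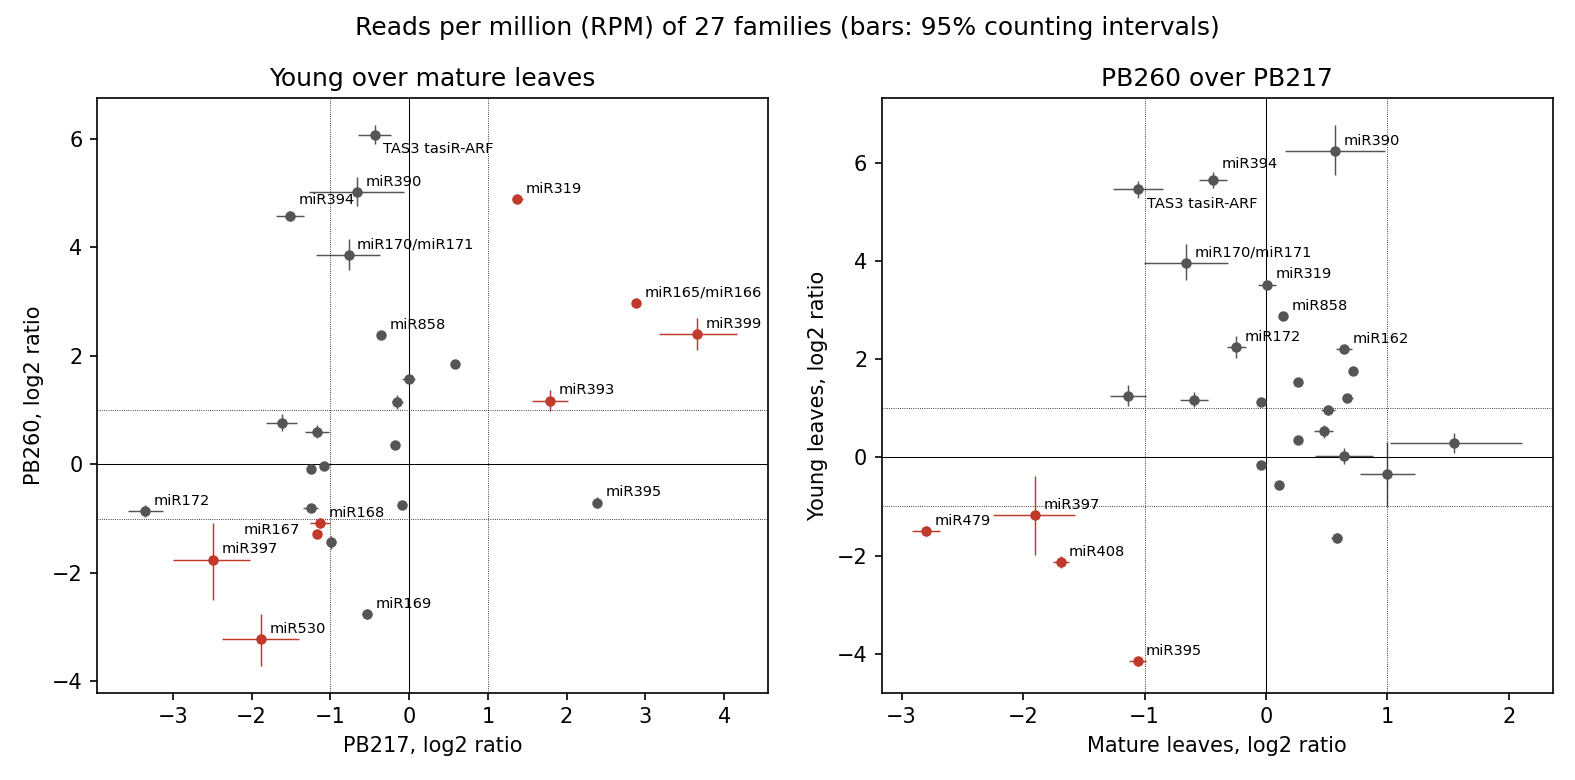
Log2 ratios of RPM for 27 families, young over mature leaves in PB217 (x) and PB260 (y) on the left, and PB260 over PB217 in mature (x) and young (y) leaves on the right, with 1 library per group and bars for 95% counting intervals. Dotted lines mark 2-fold, and red points are families at least 2-fold apart in the same direction in both pairs (8 on the left, 4 on the right). On the lower side, the PB260 ratios of miR167, miR168 and miR397 on the left, and the young leaf ratios of miR397 and miR479 on the right, change sign under other scalings.

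No family passed edgeR's quasi-likelihood test for leaf stage over the 47 families tested at an adjusted p of 0.05. There were 3 at an unadjusted p under 0.05, namely miR165/miR166 (log2 fold change 2.93, SE 0.84, adjusted p = 0.292), miR319 (3.13, SE 1.26, adjusted p = 0.554) and miR2111, which stayed under 10 RPM. DESeq2's Wald test, with its own size factors, called 11 families, 6 higher and 5 lower in young leaves. Among them were miR165/miR166 (log2 fold change 3.07, SE 0.35), miR319 (3.27, SE 0.72), miR399 (3.15, SE 0.97) and miR159 (1.35, SE 0.17) on the higher side. When adjusted over the list alone, edgeR called 0 families of at least 10 RPM in each of the 8 lists. Under 10 RPM, miR2111 of the phosphate, sulfate and nitrogen list passed by this adjustment (edgeR adjusted p = 0.0144). Without the PB217 young library edgeR called 17 families and without the PB260 young library 2, miR165/miR166 and miR395.

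At the level of single sequences, of 17861 tested edgeR called 63 higher and 246 lower in young leaves, and DESeq2's Wald test 704 higher and 791 lower. These counts also differ in scaling, since the Wald test used DESeq2's own size factors and edgeR the listed reads. Of the 63, 15 were pieces of the 5' adaptor and 3 belonged to miR165/miR166, and of the 246, 12 were from the 5' end of 18S rRNA and 6 from 5S rRNA. The 18S rRNA end measured 13705 RPM in PB217 mature and 133 in PB217 young leaves, and 21760 and 67.8 in PB260, so it was 103-fold and 321-fold lower in young leaves. Its commonest form, TACCTGGTTGATCCTGCCAGTAGT, was 177-fold lower in young leaves of PB217 and 1229-fold lower in PB260 (edgeR adjusted p = 1.4e-05), and a form longer by 2 bases, TACCTGGTTGATCCTGCCAGTAGTCA, was 228-fold and 1726-fold lower (adjusted p = 1.7e-05). The 3 sequences with the largest ratios on the higher side were adaptor pieces of 21, 19 and 18 nt that end in the CT barcode of the young libraries, the first being GTTCTACAGTCCGACGATCCT at 0.389 and 671 RPM in PB217 mature and young leaves, and 0 and 106 in PB260. The count of called sequences went from 309 to 0 under TMM or DESeq2 scaling, without the clone block, and without any 1 of PB217 mature, PB260 mature or PB260 young, and to 6137 without PB217 young. As the barcode changed with leaf stage, no value in these libraries separates the 2.

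The comparison of the clones asked which small RNAs differ between PB260 and PB217 at both leaf stages. In all 4 families met the rule, and all were lower in PB260. This depended on scaling, since under TMM and DESeq2 scaling none of the 4 met it, and miR399 and miR530 did on the higher side. The miR408 family, which targets copper proteins, was 3.23-fold lower in mature leaves (421 against 130 RPM) and 4.39-fold lower in young leaves (211 against 48.2). The miR395 family was 2.08-fold lower in mature and 17.8-fold lower in young leaves of PB260. Both kept their direction under each other scaling tried, but under TMM and DESeq2 scaling the log2 ratio of miR408 in young leaves shrank to −0.44 and −0.24, and that of miR395 in mature leaves to −0.92 and −0.83. The miR479 family was 6.95-fold and 2.83-fold lower, and miR397 3.74-fold and 2.26-fold lower, and for both the young leaf direction flipped under TMM and DESeq2 scaling. With exact matches only, miR479 had 0 reads in 3 libraries and 3 in PB217 young leaves, so that setting gives it no ratio. Both measured copper families were thus on this side, with miR395 of the phosphate, sulfate and nitrogen list and miR479 of the other conserved families. No family of the auxin, leaf and meristem, phase change, small RNA pathway, or defence and MYB lists met the rule.

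In mature leaves most families were close in the 2 clones, and of 27 only 1 was at least 2-fold higher and 6 at least 2-fold lower in PB260. The commonest, miR396, miR159 and miR167, measured 11208, 6369 and 6830 RPM in PB217 and 18363, 7640 and 6626 in PB260. In young leaves 14 families were at least 2-fold higher and 5 at least 2-fold lower in PB260. Of all 27, 19 were higher and 8 lower in young leaves, which became 25 and 2 under TMM or DESeq2 scaling and 10 and 17 under scaling by microRNA reads. The split in mature leaves was 15 higher and 12 lower, and 10 and 17 under scaling by microRNA reads. No family passed edgeR's test for clone, with 5 of 47 at an unadjusted p under 0.05, namely miR2111, 5S rRNA fragments and the Brassicaceae families miR158, miR161 and miR163. DESeq2's Wald test, with its own size factors, called 12 families, 5 higher and 7 lower in PB260. Among them were miR408 (log2 fold change −2.02, SE 0.78), miR479 (−2.26, SE 0.52), miR396 (1.13, SE 0.21) and miR390 (3.29, SE 1.17). When adjusted over the list alone, edgeR called 0 families in each list.

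Fragments of 5S rRNA were lower in PB260 at both stages, at 1393 and 213 RPM in mature leaves of PB217 and PB260 and 507 and 81.7 in young leaves. Of single sequences, edgeR called 9 higher and 36 lower in PB260, 45 of 17861, and DESeq2's Wald test, with its own size factors, 521 and 235. Of the 36, 14 came from the start of 5.8S rRNA, where the clones differed in the first bases. ATAACGACTCTCGGCAACGGA measured 2919 and 4079 RPM in mature and young leaves of PB217 and 28.2 and 132 in PB260, and AGAACGACTCTCGGCAACGGA, chosen after its values were seen, 137 and 150 in PB217 and 3921 and 2288 in PB260. The other forms selected by the rule, TAACGACTCTCGGCAACGGATAT and ATAACGACTCTCGGCAACGGATATC, were 105-fold and 91.9-fold lower in mature leaves of PB260 and 80.7-fold and 89.2-fold lower in young leaves. The 3 sequences selected on the higher side were TGAATAGAACTTTGCTTCCTT, at 0.729 and 0.468 RPM in mature and young leaves of PB217 and 77.3 and 165 in PB260 (adjusted p = 0.0109), GTTGTAAGTTGAGACTTTT, at 0.194 and 0.156 against 5.38 and 153 (adjusted p = 0.0362), and TGGTGCTGTGCTTTTAGAGAA, at 2.62 and 0.312 against 121 and 9.68 (adjusted p = 0.119, not called). The 45 calls became 0 under TMM or DESeq2 scaling and without the leaf stage block, and at most 3 with any library left out.

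The leaf stage response itself differed between the clones in many families. The TAS3 tasiR-ARF, a siRNA against auxin response factors, measured 957 RPM in PB260 young leaves and 29.4, 21.7 and 14.2 in PB217 mature, PB217 young and PB260 mature leaves. Most of these reads held mismatches. With exact matches only, it measured 55.4 RPM in PB260 young leaves and 0.486, 0.780 and 0.201 in the others, on 10, 10 and 4 reads. PB260 young leaves stayed highest, but the direction in PB217 was not kept. The microRNA that triggers it, miR390, measured 200 in PB260 young leaves and 4.18, 2.65 and 6.19 in the other libraries in that order. The miR394 family, which acts in the shoot meristem, measured 1233 in PB260 young leaves and 70.2, 24.6 and 51.9 in the others, and was the 1 of these 27 families whose response was at least 2-fold in opposite directions in the 2 clones, 2.85-fold lower in young leaves of PB217 and 23.8-fold higher in PB260, when scaled by all listed reads. Under TMM scaling miR160, miR164, miR396 and miR482/miR472/miR2118 did so as well, under DESeq2 scaling these without miR396, and under scaling by microRNA reads miR395. Of the negative control, miR161 did so too, at 11.6 and 59.5 RPM in PB217 mature and young leaves and 0.855 and 0.126 in PB260, where it had 17 and 2 reads. The miR170/miR171 family (GRAS genes) measured 85.4 against 9.28, 5.46 and 5.89, and miR858 (MYB genes) 4548 against 793, 620 and 876. In log2 units the PB260 response exceeded the PB217 response by 6.51 for the tasiR-ARF (counting interval 6.24 to 6.78), 6.08 for miR394, 5.67 for miR390, 4.63 for miR170/miR171, 3.51 for miR319, 2.73 for miR858, 2.49 for miR172 and 2.39 for miR164, which are the 8 families beyond 4-fold.

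**Figure D3:**
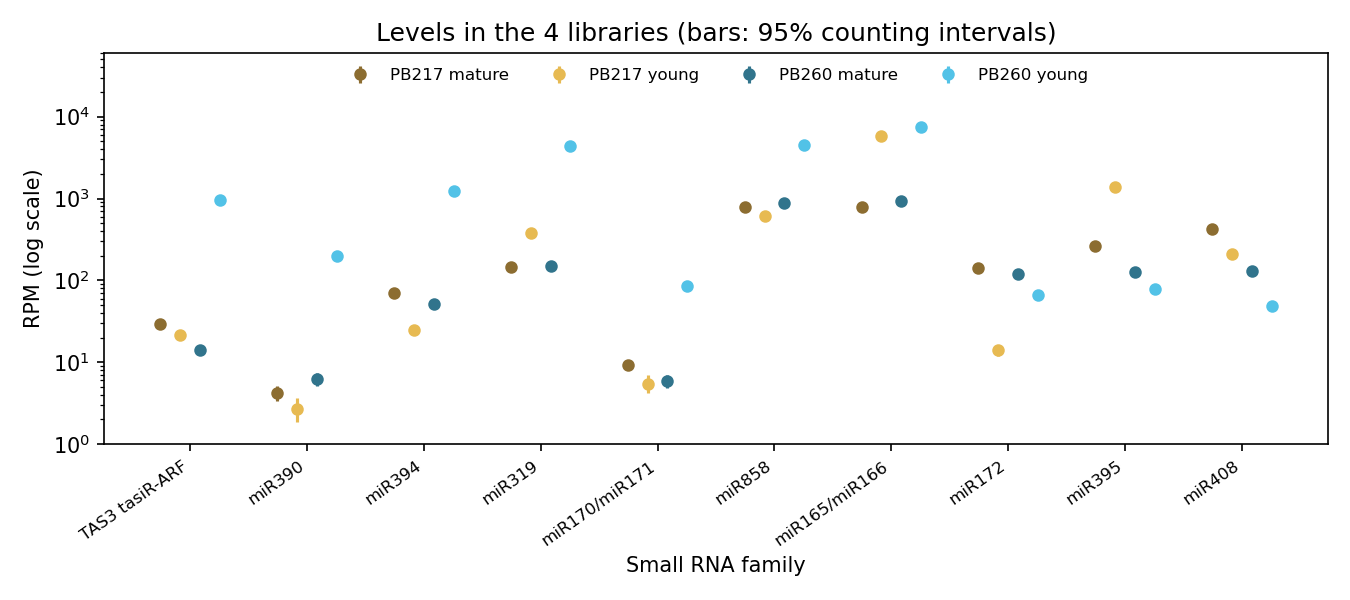
RPM (log axis) of 10 families in the 4 libraries, 1 point per library with 95% counting intervals. The PB260 young points of the TAS3 tasiR-ARF (957), miR390 (200), miR394 (1233), miR319 (4376), miR170/miR171 (85.4) and miR858 (4548) lie above the other 3 libraries, while miR165/miR166 is high in both young libraries.

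In all, 14 of 27 families had a response at least 2-fold higher in PB260, and 4 had one at least 2-fold lower, namely miR395 (−3.10), miR169 (−2.23), miR530 (−1.34) and miR399 (−1.26). The miR169 value reversed with exact matches only. It then measured 1.02 and 2.57 RPM in PB217 mature and young leaves and 0.855 and 20.5 in PB260, a larger rise in PB260. Under TMM and DESeq2 scaling 21 and 22 were at least 2-fold higher, only miR395 remained at least 2-fold lower, and miR530 and miR399 changed sign, while under scaling by microRNA reads 8 were higher and 8 lower by 2-fold. The median of the 8 members was 4.07, and ranged from 3.11 to 5.73 over the scalings. Passenger strands, the partners of the mature strand in the duplex, differed too. The strand listed as miR171 passenger measured 1816 RPM in PB260 young leaves and 7.63, 15.0 and 5.28 in PB217 mature, PB217 young and PB260 mature leaves. Of its reads and those of the miR170/miR171 family together, it made up 95.5% against 45.1%, 73.4% and 47.3%. As a family sums several loci, this is not the share of 1 duplex, and the strand names follow the list alone. The passenger strands of miR390 and miR172 were 3.19-fold and 2.19-fold lower in young leaves of PB217 and 10.2-fold and 4.41-fold higher in PB260. In PB217 mature and young leaves they had 41 and 8 reads and 88 and 25 reads. The counting intervals of the PB217 log2 ratios, −2.98 to −0.56 and −1.84 to −0.48, did not secure a 2-fold drop. With 1 library per group no test of the interaction was possible, and 6 of the 8 members were highest in the PB260 young library, which also had the fewest 18 to 20 nt reads (23.4%) and the most tRNA-Ala fragments. The other 2 were highest in PB217 mature and lowest in PB217 young leaves, miR172 at 142, 14.0, 120 and 66.1 RPM and miR164 at 58.8, 19.2, 26.8 and 45.7 in PB217 mature, PB217 young, PB260 mature and PB260 young leaves.

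Set against random lists of unlisted 20 to 22 nt sequences of like abundance, the leaf and meristem list lay at the 2.32 percentile for leaf stage in PB217 and above all 10000 random lists in PB260. Its median log2 ratios were −1.20 and 2.77, against −1.05 for the middle random list in PB260. The auxin list lay at the 5.32 and 99.97 percentiles, the phosphate, sulfate and nitrogen list at 99.97 and 64.9, the small RNA pathway list at 3.03 and 63.5, and the other conserved families at 36.3 and 73.1. Between clones in mature leaves these 5 lists lay at 82.6, 60.5, 94.0, 93.1 and 54.6, and in young leaves at 99.7, 98.7, 15.0, 97.2 and 72.4. All 27 families together lay at the 0.01 and 99.99 percentiles for leaf stage in PB217 and PB260, and between clones at 92.5 in mature leaves and above all 10000 random lists in young leaves, so such placements were not particular to single lists. The phase change, copper, and defence and MYB lists had 2 measured members each and were not placed.

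The commonest sequences outside the families were fragments or small RNAs that joined no listed family under the matching rule. Of 24 nt, GGGGATGTAGCTCAAACGGTAGAG measured 36672 RPM in PB260 young leaves and 2453, 899 and 2666 in PB217 mature, PB217 young and PB260 mature leaves. GGGGATGTAGCTCAAATGGTAGAG measured 12856 against 992, 434 and 1103, and the 18S rRNA form above completed the 3. Of 22 nt, TTTGCAGTTCGAAAGTGGAAGC measured 29867 in PB260 young leaves and 2751, 3527 and 5282 in the other libraries. AGATGGGTGGCTGGGCAAGAAG was 39.96-fold higher in young leaves of PB217 (108 against 4322 RPM) and 42.4-fold higher in PB260 (108 against 4590), with an edgeR adjusted p of 0.0068. CACGTCTGCCTGGGTGTCACGC measured 1736, 1710, 2238 and 1235 in PB217 mature, PB217 young, PB260 mature and PB260 young leaves. Of 21 nt, AACAGACCGGTAGACTTGAAC measured 2116, 3560, 2282 and 1444, and TTTCATTATCTGTTCGACCTG 1045, 1314, 2098 and 3208, beside the 5.8S rRNA form above.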

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

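The tests of the leaf age explanation, of the barcode behind the 8 families, of scaling, of labels and of leaf stage, that of a rubber tree origin and that of PB217 young leaves alone were chosen after the results were seen. The comparison of 5' with 3' neighbours and the search for 6 further Brassicaceae small RNAs were fixed before their results were seen. No group had the 4 samples needed to look for an outlying library.

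The miR394 family, the miR390 passenger strand and the miR172 passenger strand went in opposite directions with leaf stage in the 2 clones. The PB260 response exceeded that of PB217 by 6.08, 5.02 and 3.27 log2 units, and the difference was not tested because no replicates exist. The control family miR161 went the opposite way (−5.12), with 17 and 2 reads in PB260, and is not part of what follows. The first 3 go with a wider pattern, in which 8 families had a response beyond 4-fold higher in PB260. The barcode is argued against as the whole cause by the design, because both clones carry the same barcode at each leaf stage, so that its bias would be alike in both, whereas the members' median log2 ratio of PB260 young to PB217 young leaves was 3.74 (quartiles 2.72 and 5.51). The members were chosen for a difference in response, so this value gives the size of what the barcode would have to explain and is no independent test. No scaling tried removed the difference in 5 members (TAS3 tasiR-ARF, miR394, miR390, miR170/miR171 and miR319), which stayed beyond 4-fold under each, at a log2 difference of 2.55 or above. These 5 were set apart by that outcome, so it describes them and cannot exclude scaling as a cause. For miR858, miR172 and miR164 the difference fell to at most 1.77 under scaling by microRNA family reads, and the part played by scaling stays open. These libraries do not show which scaling is right for any of the 8. An exchange of a mature and a young library after the barcode was added is argued against by the adaptor reads, of which at least 72.1% carried the labelled barcode in every library. A wrong clone label, or a wrong leaf label before that step, stays open. At least 93.0% of the 5.8S rRNA starts went with the clone label, but these starts were chosen from the same libraries by their labels. The stage of the young leaves, RNA or library quality, or another difference between the clones may lie behind the 8 families. These cannot be told apart here, since the labels give no stage and each group is 1 library. The PB260 young library, where 6 of the 8 were highest, held 23.4% of its reads at 18 to 20 nt. PB217 mature, PB217 young and PB260 mature leaves held 44.8%, 41.2% and 35.3%.

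MicroRNAs known from Brassicaceae appeared in PB217 at 29.4 RPM summed over the first list of 5, in data meant as a negative control. This and the other summed values in this paragraph count exact matches only. With up to 2 mismatches, as for the families above, levels in PB217 mature and young leaves were higher. They were 24.5 and 35.5 RPM for miR158, 11.6 and 59.5 for miR161, and 0.874 and 16.6 for miR163. By exact matches the same list measured 1.09 RPM in PB260, which is 27-fold lower. This does not exclude sequences encoded by the rubber tree, since sequences that both clones encode can differ in level, so that explanation stays open. Of 6 further Brassicaceae small RNAs, 3 were found exactly at 3 or more reads in PB217 mature leaves and 0 in PB260. This is consistent with a trace of reads from another plant in the PB217 mature library, as a hypothesis, while how it got there stays open. In PB217 young leaves 0 of the 6 were found, although the first list was higher there than in PB217 mature leaves. By exact matches it measured 41.1 against 22.1 RPM, with miR158 at 27.2 against 17.4 and miR161 at 10.52 against 3.74. Whether that library holds reads of the same makeup thus stays open.

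Pieces of the 5' adaptor were read as small RNAs at 232 RPM in PB217 mature, 5976 in PB217 young, 206 in PB260 mature and 545 in PB260 young leaves. They are outside the small RNA comparisons but take part in the count of called sequences.

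Of 1536 sequences with at least 100 RPM in a library, 908 (59.1%) moved in the same direction with leaf stage in both clones. Of the 1536, 75 were at least 2-fold higher and 289 at least 2-fold lower in both young libraries, and 52 moved at least 2-fold in opposite directions. For clone 912 (59.4%) moved in the same direction at both leaf stages. Sequences that differ by 1 base at the 5' end, where the barcoded adaptor joins, differed in their leaf stage ratio 1.31 times as much as those that differ by 1 base at the 3' end (bootstrap interval 1.26 to 1.37), against 1.20 times (1.15 to 1.24) for the clone ratio, whose libraries share barcodes. The larger excess for leaf stage is what a part played by the barcode would give. The clone ratio showed an excess without any barcode difference, however. The bootstrap intervals cover sequences within these 4 libraries, which are not independent, and not the spread between libraries. The gap between the excesses thus has no replicate check. Leaf age and barcode cannot be told apart for the 908 sequences, because they change together in all 4 libraries.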

How the results depend on the processing

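Under TMM scaling the count of families at least 2-fold apart in the same direction went from 8 to 5 for leaf stage, and under DESeq2 scaling to 6, of which miR395 was not among the 8. For clone it went from 4 to 2 under TMM and DESeq2 scaling, where none of the 4 remained and the 2 were miR399 and miR530, both higher in PB260. The PB260 leaf stage ratio turned positive under TMM and DESeq2 scaling for miR167 (0.33 and 0.50) and miR168 (0.54 and 0.71), and under DESeq2 scaling for miR397 (0.028). The clone ratio in young leaves turned positive for miR397 (0.52 and 0.72) and miR479 (0.19 and 0.39). These reversals follow from the shift of scale given in the report. The leaf stage directions of miR165/miR166, miR319, miR399, miR393 and miR530 were kept under all 4 other scalings. Of the alternatives to the ratios of leading families, 51 stayed within the counting interval, 57 moved beyond it and 9 reversed. With exact matches only, 7 families were at least 2-fold apart for leaf stage, of which 6 were among the 8. The log2 ratio of miR393 in PB260 went from 1.17 to 0.39, miR399 fell under 10 RPM with 0 reads in PB217 mature leaves, and miR169 entered as higher in young leaves (1.02 against 2.57 RPM in PB217, 0.855 against 20.5 in PB260). For clone 3 of the 4 remained, since miR479 had too few exact reads for a value. Families called by edgeR numbered 1 in each comparison under TMM or DESeq2 scaling (miR2111 for leaf stage, miR163 for clone), 4 for clone with no replicate block (miR390, miR161, miR163 and the miR171 passenger strand) and 1 for clone without a filter (miR173), all named after their values were seen. DESeq2's Wald test, which also changed the scaling to its own size factors, called 11 for leaf stage and 12 for clone. Called sequences numbered 0 in both comparisons under TMM or DESeq2 scaling and with no replicate block, 1495 and 756 by DESeq2's Wald test, and 164 and 11 at a mean of 1 RPM, where more sequences were tested. At 50 RPM 60 were called for leaf stage, with fewer sequences tested. For the test counts the cause was not tested otherwise. With each library left out in turn, a fit that assumes the lone library varies like the others called 0 to 17 families and 0 to 6137 sequences for leaf stage, and 0 to 6 families and 0 to 3 sequences for clone. The high leaf stage values came without PB217 young, when PB260 young is the lone young library, and the 6 families for clone came without PB260 mature.

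The 24 nt share in PB217 mature, PB217 young, PB260 mature and PB260 young leaves was 39.8%, 40.2%, 50.4% and 51.8% by distinct sequences, 12.5%, 14.5%, 20.1% and 32.4% without listed rRNA and tRNA, 12.2%, 14.5%, 19.8% and 28.3% without these and sequences like tRNA-Ala (added after seeing the data), and 13.1%, 16.3%, 20.9% and 35.3% without the 100 commonest sequences, with PB260 young highest each time. Leaving out sequences read once was not run, since none is listed. For staying under 10 RPM, 6 of 33 families were left out of the 2-fold counts, of which 3 (miR398, miR827 and miR2111) had enough reads for edgeR's test. The families miR477 and miR1446 had 0 reads in each library and miR828 had 3, all in PB260 young leaves. For these, low depth and absence cannot be told apart. Absence from a file allows 1 read.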

Other observations

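The values in this part were looked at after seeing the data. The leaf stage ratio of miR165/miR166 reads differed by start site. The start is the base joined to the barcoded adaptor, so leaf stage and barcode cannot be told apart in these ratios. Reads that begin at the listed first base were higher in young leaves by 4.16 log2 units in PB217 and 3.85 in PB260, reads that begin 1 base upstream by 1.74 and 5.10, and reads that begin 2 bases upstream by 0.92 and 1.87. Shares of passenger strands were taken of the reads of the strand and of its whole family together. The passenger strand of miR166 made up 28.5% in PB217 mature, 0.929% in PB217 young, 19.1% in PB260 mature and 4.89% in PB260 young leaves. The passenger strand of miR396 took 7.05%, 14.8%, 3.47% and 10.96% in the same order, and that of miR168 6.97%, 12.4%, 4.17% and 30.0%. A 21 nt sequence resembling a miR396 passenger strand, GTTCAAGAAAGCTGTGGGAGA, measured 1396 RPM in PB260 young leaves and 1.60, 3.82 and 3.52 in PB217 mature, PB217 young and PB260 mature leaves.

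Fragments of tRNA-Gly measured 2274, 2650, 1730 and 371 RPM in PB217 mature, PB217 young, PB260 mature and PB260 young leaves, so they were lowest in the library where tRNA-Ala fragments were highest. Fragments of tRNA-Asp measured 193, 117, 135 and 131, and those of tRNA-His 81.7, 63.0, 27.7 and 52.5. With the barcode read behind the adaptor pieces, 72.1%, 99.5%, 98.0% and 99.7% carried the labelled barcode, so PB217 mature leaves held the largest share of the other barcode. Among 5.8S rRNA starts that differ between clones, 96.9%, 97.9%, 98.9% and 93.0% were those commonest in the labelled clone. Across neighbouring sequences, the difference in leaf stage ratio between 5' neighbours correlated between the 2 clones at r = 0.65 over 8263 pairs, and between 3' neighbours at r = 0.44 over 8020 pairs. These are correlations across sequences, which are not independent replicates.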
